A study of Mus musculus with 2 samples.

How the data were processed

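Chromatin accessibility was measured by ATAC-seq in inflammation-experienced regulatory T cells of a male mouse of the strain Foxp3CreERT2 x Rosa26YFP aged 6 months. The labels list 2 samples, technical replicates 1 and 2 of biological replicate 1, from the same donor. They formed 1 group. Per the text files deposited with the samples, which were identical for both, the authors derived 3 lists of peaks on mm10 from 1 filtered alignment: pseudoreplicated peaks, IDR-thresholded peaks and IDR-ranked peaks. The first and second list also drew on another file whose content is not named. Since the same lists are given for both samples, they were taken to pool the libraries. Aligner, peak caller, versions, read filters, the shift of reads for the Tn5 insertion and the IDR threshold are not given in the sources used here, and neither are read counts, so the depth of each library is unknown and no interval or detection limit could be based on it. Values per library were not analysed here, since no list held values labelled by library.

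Each peak in the deposited lists carries a fold enrichment over background (a linear ratio), a −log10 p-value and a −log10 q-value as the authors' peak caller gave them, and the position of its summit. Their units were taken from the values and the order of the columns. What the background of the fold was is not stated, and a local background would make the fold and the width of a peak depend on its surroundings. In the ranked list the deposited score, a whole number up to 1000, follows the −log10 of the global IDR, and the authors also list the −log10 p in each of the 2 sets ranked against each other. The lowest score in the thresholded list was 540, which corresponds to an IDR of 0.05. All 58138 peaks of that list were found in the ranked list, where 58307 had an IDR at or below 0.05; of the 169 others, 58 lay on sequences outside the assembled chromosomes and 111 in 49 regions of the assembled chromosomes. The fold, score and p-values were used only to describe, rank or filter peaks within a list.

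Choices made before the data were examined were the gene lists, the motifs, the main comparisons, the windows, the rule for naming genes and all alternatives except 1 described below. Tests of technical explanations were chosen later, most of them after the pattern concerned had been noticed. Peaks that overlapped or touched were merged into regions, the peak with the greatest fold gave a region its fold and summit, and the greatest −log10 p of its peaks was kept. That height means the fold, rather than the −log10 p, was settled once the lists had been opened. The IDR-thresholded list was the main list. Positions were used with GRCm38.p6 and the GENCODE M21 annotation, after the names of the 21 chromosomes in the lists were matched to the reference and 0 peaks were found to run past a chromosome end. A region was put in the first class that held its summit: promoter (within 1000 bp of a protein-coding transcript start), exon, intron or intergenic. Shares have 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only.

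A gene was counted as having a promoter region if a region overlapped the 1000 bp on either side of any of its protein-coding transcript starts. Each region was assigned to the gene with the nearest start within 100 kb, and the territory of a gene is the sequence that would be assigned to it by this rule. For each of the 17 gene lists (293 entries, 288 genes, 5 of them in 2 lists) the share of genes with a promoter region was set against 10000 random lists matched gene by gene on the decile of promoter CpG observed over expected, and the mean number of regions per locus against 10000 random lists matched on the decile of territory length. The CpG ratio was taken from the 500 bp on either side of the 5' end of the gene record. That end can lie far from the transcript starts used for the promoter call, as at Ctla4 (chromosome 1, 60887000 against 60909025 and 60909171). Clec7a and Ahsp were not in the gene set used, and a few members of the lists are counted with their list but not reported here by name. The bounds of 2.5 and 97.5 percentiles were not part of the written design, and neither these nor the motif intervals were adjusted for the number of lists and motifs. No p-value was computed, since genes are not replicates and there was 1 biological replicate.

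For 34 consensus motifs, the share of summits with a match within 50 bp was divided by the share in windows of the same size centred 500 bp to either side. The same ratio for up to 20 versions of the motif with its letters in another order was subtracted on the log2 scale. Orders with the same number of CG pairs were used where there were enough of them. The interval came from 1000 bootstrap draws of regions. A motif was called enriched or depleted if the interval excluded 0; this criterion, and the limit of 20 matches, were settled once motif values had been seen. The intervals cover the choice of regions only, and the sequence preference of Tn5 was not modelled. X-linked and autosomal promoters were compared by the difference in share, with a Newcombe interval, and by the difference in median fold, with a bootstrap interval over regions.

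The named genes were those of the fixed lists, the 20 protein-coding genes with most regions (ties by symbol), the 10 regions with the greatest fold, and the regions of Foxp3, Il2ra, Ctla4, Ikzf2, Prdm1 and Il10. Regions that overlap or lie within 5 kb of these genes but were assigned to a neighbour, and the separate starts of Foxp3, were added once the first values had been seen. The regions with a −log10 p over 1000 were also chosen from their values. Each result was recomputed under the alternatives: the pseudoreplicated list, the upper 50% of regions by fold (for X against autosomes, an IDR 4 times smaller), peaks counted singly, promoter windows of 500 and 2000 bp, only the 5' end of each gene record, unmatched random lists, an assignment limit of 50 kb, loci without their own promoter regions, motif windows of 100 bp, flanks 2000 bp away, merging within 150 bp, and assembled chromosomes only. Leaving out a replicate was not possible with pooled lists. An alternative without regions that align to the mitochondrial genome was chosen after seeing the data. For it, regions were aligned to the mitochondrial sequence of GRCm38 with BLAST+ 2.17.0 and counted from 90% identity over 50% of their length.

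The calculations were tested on simulated data. For motifs, the bases of summits and flanks alike were drawn independently and with equal frequency. How often motifs are called where base composition differs between summit and flank was thus not tested. All 4 motifs planted in 5000 simulated regions were called, with a share off by at most 0.096 percentage points, and 23 of 340 tests of motifs that had not been planted were called (6.76%), more than the 5% expected, as were 3 of the 30 motifs not planted in the simulation that held the 4. Of 10 lists of 20 genes made from 200 changed genes among 21822, all 10 lay above the 97.5 percentile of 1000 random lists for promoters and all 10 for regions per locus. Of 200 unchanged lists, 5 lay above and 6 below the bounds for promoters, and 3 and 7 for regions per locus. Distances to the nearest start were right for 500 of 500 positions and promoter calls for 715 of 715 genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.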

Results

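ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, was performed on inflammation-experienced regulatory T (Treg) cells of an adult male mouse aged 6 months. Treg cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The mouse carried Foxp3CreERT2, which places a drug-inducible Cre recombinase under the control of Foxp3, and the Cre reporter Rosa26YFP, a combination used to mark Treg cells with a yellow fluorescent protein. The labels state neither which inflammation the cells had met nor how they were isolated. The 2 samples were technical replicates of 1 biological replicate and formed 1 group, so no comparison between conditions was possible. Resting Treg cells and other T cells were not analysed here.

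The deposited data were 3 lists of accessible regions, taken here to pool both libraries. They were a pseudoreplicated list, a list thresholded on the irreproducible discovery rate (IDR), and a ranked list with the IDR of every candidate. No list held a value labelled by library, so spread between libraries or mice could not be measured. The sequencing depth is unknown, and the intervals given here cover counting or the choice of regions only. The fold enrichment and −log10 p of each region are the authors' own values, and all positions are GRCm38 (mm10), counted from 1. Distances from a transcript start are negative upstream of it.

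The Treg cells carried 29415 accessible regions in the IDR-thresholded list, which together covered 20.9 Mb, or 0.766% of the assembled genome. The regions had a median width of 659 bp (interquartile range 452 to 912 bp) and a median fold enrichment over background of 13.1 (interquartile range 9.30 to 17.5). More than 1 summit was called in 55.9% of them. The pseudoreplicated list held 52972 regions with a median width of 456 bp and a median fold enrichment of 8.40, and the ranked list held 53708. Of the 29415 regions, 29364 (99.8%) were also in the pseudoreplicated list with the same start and end. The 23608 pseudoreplicated regions outside the IDR-thresholded list were shorter and lower, with a median width of 300 bp, a median fold enrichment of 5.25 and a median −log10 p of 14.7. In the ranked list, the −log10 p in the first and second set of reads that were ranked against each other had a Spearman correlation of 0.746 across 87840 summits and lay within 2-fold of each other in 81.1% of them. At an IDR over 0.05 the correlation was 0.397. Whether the sets were the libraries or parts of the pooled reads is not known. These are correlations across summits of a single biological replicate, and summits are not independent replicates.

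Accessible regions gathered at promoters. Of the 29415 regions, 10802 (36.7%, 95% exact binomial interval 36.2 to 37.3%) had their summit within 1000 bp of a protein-coding transcript start, a space that makes up 2.44% of the genome, which is a 15.1-fold excess (14.8 to 15.3). Exons outside promoters held 4.96% of the regions (1.19-fold, 1.13 to 1.25), introns 33.7% (0.843-fold, 0.829 to 0.856) and intergenic sequence 24.6% (0.461-fold, 0.452 to 0.470). Promoter regions were wider, with a median of 909 bp against 540 bp in introns, and higher, with a median fold enrichment of 15.4 against 11.6 in exons, 11.6 in introns and 12.6 in intergenic sequence. Among the 23608 pseudoreplicated regions outside the IDR-thresholded list, 13.3% (12.8 to 13.7%) lay at promoters, a 5.44-fold excess, and 48.3% lay in introns. The size of the promoter excess depended on the window, and was 25.6-fold at 500 bp and 8.85-fold at 2000 bp.

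**Figure D1:**
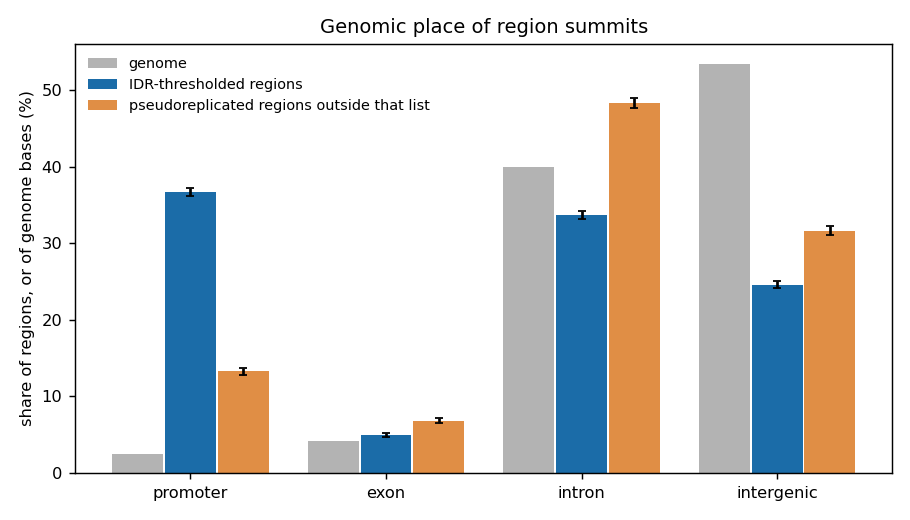
Share of region summits (percent, vertical axis) at promoters, exons, introns and intergenic sequence, for the genome's own bases (grey), the 29415 IDR-thresholded regions (blue) and the 23608 pseudoreplicated regions outside that list (orange); error bars are 95% exact binomial intervals. Promoters hold 2.44% of the genome, 36.7% of the IDR-thresholded regions and 13.3% of the others.

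Of 21822 protein-coding genes, 10847 (49.7%) had an accessible region within 1000 bp of a transcript start. The share was 83.7% among genes in the upper 3 deciles of promoter CpG content and 11.6% among those in the lower 3. CpG content was taken around the 5' end of each gene record, which for some genes lies apart from the transcript starts scored. With each region assigned to the nearest transcript start within 100 kb, a gene had 1.25 regions on average, 44.6% of genes had none, and 219 genes had 10 or more. Fixed gene lists were therefore compared with 10000 random lists of the same size, matched on promoter CpG decile for the share of accessible promoters and on the decile of genomic territory for the number of regions per locus. With 1 biological replicate the resulting percentiles describe these pooled libraries and are not p-values. An accessible promoter is not a measure of expression.

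Genes of the list taken to represent the Treg core had accessible promoters and many regions per locus. In the Treg core list, 22 of 24 genes (91.7%) had a promoter region, above the random lists (25 to 58.3%, percentile 100), and the median locus held 7 regions (mean 6.33, random lists 0.708 to 2.29, percentile 100). Promoter fold enrichment was 11 at Il2ra, the high-affinity interleukin-2 receptor chain, 6.20 at Ctla4, an inhibitory receptor, 4.92 at Ikzf2, which encodes Helios, and 25 at Entpd1, an ectonucleotidase. The 2 genes without a promoter region were Tnfrsf18, which encodes the receptor GITR, and Il10, an inhibitory cytokine, with 5 and 7 regions in their loci. Icos had 14 regions and Tigit had 12. Not every list member is particular to Treg cells, and Ptprc, for one, is expressed by leukocytes in general. When regions were limited to the upper 50% by fold enrichment, the promoter percentile of this list fell to 18.3, on the other side of the random lists' middle, while its locus percentile was 99.99.

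Genes of effector and tissue Treg cells had many regions, with fewer accessible promoters. In that list 13 of 27 genes (48.1%) had a promoter region, within the range of random lists (22.2 to 51.9%, percentile 92.9), and the mean locus held 3.89 regions (random lists 0.815 to 2.48, percentile 100). Regions numbered 14 at Irf4 and 9 at Prdm1, transcription factors of effector Treg cells, 13 at Cd44, an activation marker, and 8 at Gata3. Promoter fold enrichment was 14.6 at Prdm1, 8.32 at Irf4, 15.9 at Batf, 12.7 at Maf, 19.8 at Areg, an epidermal growth factor family ligand involved in tissue repair, and 8.79 at Pdcd1. Promoters without a region included those of Klrg1, Il1rl1, Gzmb, Cxcr3 and Tbx21, and no region was assigned to Cxcr3 or Pparg. The promoter percentile of these genes was 100 in the larger pseudoreplicated list and 2.585, on the other side of the middle of the random lists, in the upper 50% of regions by fold enrichment.

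Genes of naive and resting T cells had many regions per locus as well. The promoter share was 13 of 18 (72.2%, random lists 50 to 83.3%, percentile 75.7), and the mean locus held 9.44 regions, the highest count of the 17 lists, not corrected for territory length (random lists 0.778 to 3.28, percentile 100). Foxp1 had 29 regions and Bach2 had 28, both repressors that restrain effector differentiation. S1pr1, a receptor for exit from lymph nodes, had 15, Lef1 had 14, Foxo1 had 10, and Il7r, the interleukin-7 receptor chain, had 9. Tcf7, which encodes TCF1, had 8 regions but none at its promoter. In the upper 50% of regions by fold enrichment the promoter percentile of this list was 0.015, and in the pseudoreplicated list it was 98.8.

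T cell identity genes, signalling genes and interferon genes were accessible as well. In the pan T cell list 18 of 20 genes (90%) had a promoter region (random lists 10 to 45%, percentile 100), with 7.15 regions per locus on average (percentile 100), led by Runx1 with 19, Bcl11b with 16 and Ets1 with 15; the exceptions were Cd4 and Thy1. All 15 genes of the NF-kB and NFAT list had a promoter region (percentile 99.955), with 7.07 regions per locus (percentile 100), including 17 at Nfatc1, 16 at Nfkb1 and 15 at Nfkbiz. Of the AP-1 and BATF family 15 of 17 genes had one, at the edge of the random lists (47.1 to 88.2%, percentile 97.575), with 4.65 regions per locus (percentile 100). Of interferon response genes 17 of 18 had one (percentile 100), and Oas2 was the exception. Their promoter fold enrichment was highest at Stat2 (28.3), Ifit1 (26.5) and Bst2 (26.1), with a median of 14.4 over the 17 promoters. Random lists of accessible promoters had a median of 16.4 (percentile 13.1). The interferon loci held 2.11 regions on average (random lists 0.444 to 1.5, percentile 99.98). Several of these calls depended on the setting. Among the upper 50% of regions by fold enrichment, the promoter percentiles of the AP-1 and BATF family (0.070) and of the NF-kB and NFAT list (1.255) lay below the random lists instead of above, and the pan T cell locus percentile was 95.115. The AP-1 and BATF promoter percentile also fell within the random lists in the pseudoreplicated list (92.735), with a window of 2000 bp (96.815) and with gene 5' ends only (94.52). That of the NF-kB and NFAT list was 89.98 with gene 5' ends only, and the interferon locus percentile was 94.81 with unmatched random lists.

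Effector cytokine genes were accessible in part. A promoter region was present at 6 of 15 genes (40.0%, random lists 6.67 to 46.7%, percentile 89.97), namely Il2, Ifng, Il4, Il21, Lta and Tnfsf11, with promoter fold enrichments of 10.5 at Il2, 10.3 at Ifng and 11.1 at Il4. The mean locus held 2.67 regions (random lists 0.467 to 2.33, percentile 99.345), with 12 at Ifng, 7 at Tnfsf11 and 6 at Il21. No region was assigned to Il17a, Il17f, Il22 or Il3. In the upper 50% of regions by fold enrichment the locus percentile dropped to 69.6 and the promoter percentile to 2.94, and with summits counted singly the locus percentile was 96.005. The promoter percentile rose past the upper bound in the pseudoreplicated list (98.91) and with gene 5' ends only (97.62).

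Lists of other cell types were at or below the level of random lists in both measures, apart from CD8 and NK cytotoxic genes. In that list 4 of 15 genes had a promoter region (percentile 78.5), and the mean of 2.20 regions per locus was at the edge of the random lists (0.533 to 2.20, percentile 97.56), carried by Fasl with 15 regions and Klrb1c with 10; Cd8a, Klrd1, Ncr1 and Nkg7 had none. The locus call of this list was lost in the upper 50% of regions by fold enrichment (68.7), with summits counted singly (96.21), within 50 kb (96.31) and with unmatched random lists (94.79). The promoter counts were 3 of 16 for B cell genes (percentile 38.2), 4 of 17 for myeloid genes (36.1), 3 of 12 for dendritic cell genes (16.7) and 2 of 11 for erythroid genes (29.1), with locus percentiles of 13.75, 38.7, 49.3 and 8.30. With unmatched random lists the promoter percentiles of the B cell (0.655), myeloid (1.61) and erythroid lists (2.05) fell below the bound. The myeloid one was also below it in the upper 50% of regions (1.03). With summits counted singly, the locus percentiles of the erythroid (1.22) and neuron lists (2.12) fell below it. No region was assigned to Ms4a1, Cd79a, Csf1r, Lyz2, S100a8, Itgax or Flt3. Neuron genes (2 of 16, percentile 0.025) and muscle genes (1 of 15, percentile 0.545) lay below the random lists for promoters, liver genes (1 of 17, percentile 2.695) at their lower edge, and liver (percentile 1.38) and muscle genes (percentile 0.73) below them for regions per locus. The promoter percentile of liver genes fell below the bound in the pseudoreplicated list (0.785), in the upper 50% of regions (2.345), with a window of 2000 bp (1.79) and with unmatched random lists (0.015). Their locus percentile was 4.5 in the pseudoreplicated list and 25.6 without regions at the own promoter. That of muscle genes was 3.32 in the upper 50% of regions and 11.4 without own promoters, and their promoter percentile was 7.375 with gene 5' ends only. All 18 housekeeping genes had a promoter region (percentile 99.99), with 2.5 regions per locus (percentile 99.865); the promoter percentile was 90.3 in the upper 50% of regions. In all, 6 of the 17 lists lay above the middle 95% of random lists and 2 below it for promoters, and 10 and 2 for regions per locus; these bounds were not adjusted for the number of lists.

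**Figure D2:**
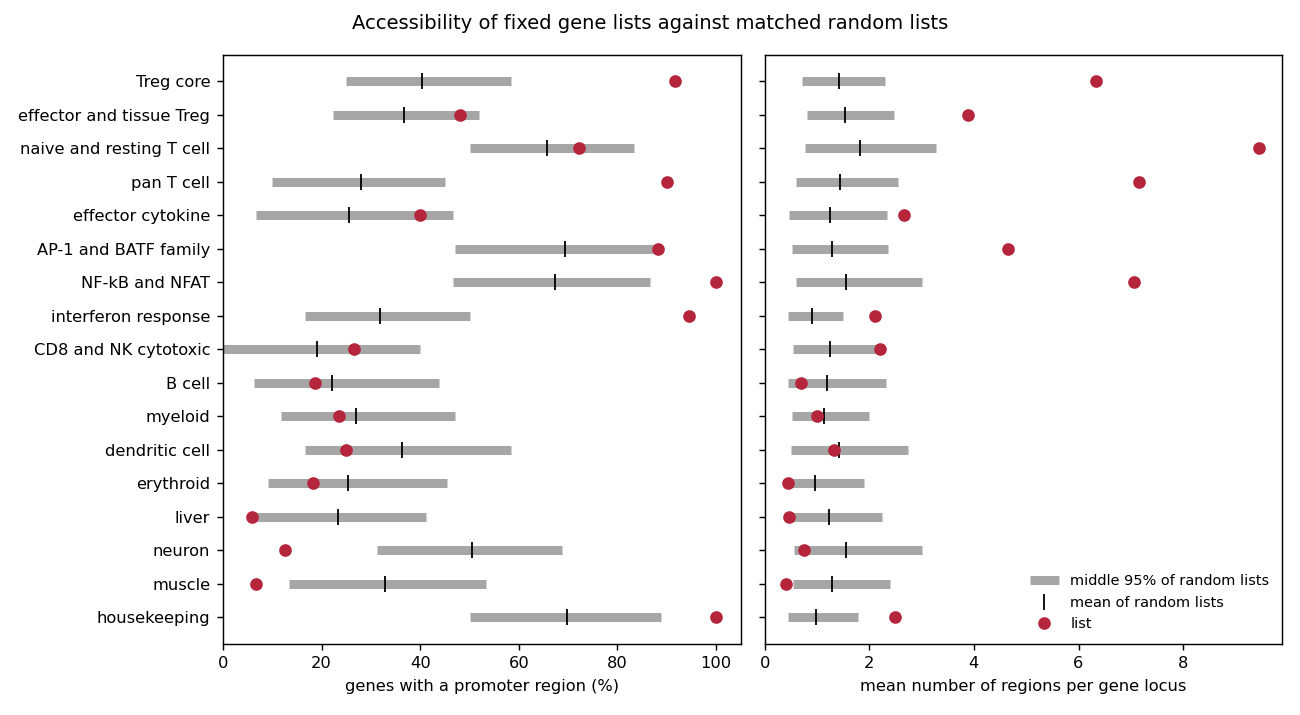
Share of genes with a promoter region (percent, left) and mean number of regions per gene locus (right) for the 17 gene lists (red points), with the mean (black line) and the middle 95% (grey bar) of 10000 matched random lists. The Treg core (91.7%), pan T cell (90%) and interferon response (94.4%) points lie to the right of the bar for promoters, and the naive and resting T cell list has the highest mean number of regions, 9.44.

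The Foxp3 gene (chromosome X, 7573644 to 7595245, plus strand) overlapped or lay within 5 kb of 3 regions. The highest, at X:7583663-7584417 with a fold enrichment of 10.8, lies in an intron. The other 2, at X:7574054-7574984 (fold enrichment 9.62) and X:7572441-7572929 (4.42), surround the most upstream of 7 annotated Foxp3 transcript starts and have their summits nearest to a start of the neighbouring gene Ppp1r3f, so the promoter call of Foxp3 rests on a region shared with another gene. Around the 3 starts between X:7579567 and X:7579676 there was no region in the IDR-thresholded or the pseudoreplicated list. The ranked list had X:7579537-7579694 there, with a fold enrichment of 1.95 and a −log10 p of 5.42.

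At the other 5 loci examined in detail, the highest region lay outside the promoter windows. Il2ra (chromosome 2, 11642807 to 11693193) had 8 regions, of which 7 were intronic; the promoter region 2:11642249-11643050 had a fold enrichment of 11 and the intronic region 2:11653155-11653730 had 11.4. Ctla4 (chromosome 1, 60887000 to 60915832) had 16 regions, with fold enrichments of 6.20 at the promoter, 17.3 at 1:60868083-60868747, at −40439 bp from a transcript start, and 15.3 at 1:60940821-60941555, at 32033 bp from one. Ikzf2 (chromosome 1, 69531214 to 69687245, minus strand) overlapped or was assigned 13, with 16.6 in the intronic region 1:69544139-69544653, 17.2 at 1:69752582-69753401, at −65677 bp from a start, and 4.92 at the promoter. Prdm1, which encodes Blimp-1 (chromosome 10, 44437177 to 44528501, minus strand), had 9, with 25.3 in the intronic region 10:44482940-44483594, 23.0 at 10:44529220-44530058 just beyond the 5' end of the gene and 14.6 at the promoter region 10:44458393-44459189. Il10 (chromosome 1, 131019845 to 131024974) had none at its promoter and 7 around it, including 18.4 at 1:131010188-131011375, at −9142 bp from its start, 16.8 at 1:130993345-130994271, and 6.99 and 9.70 in the gene's introns.

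**Figure D3:**
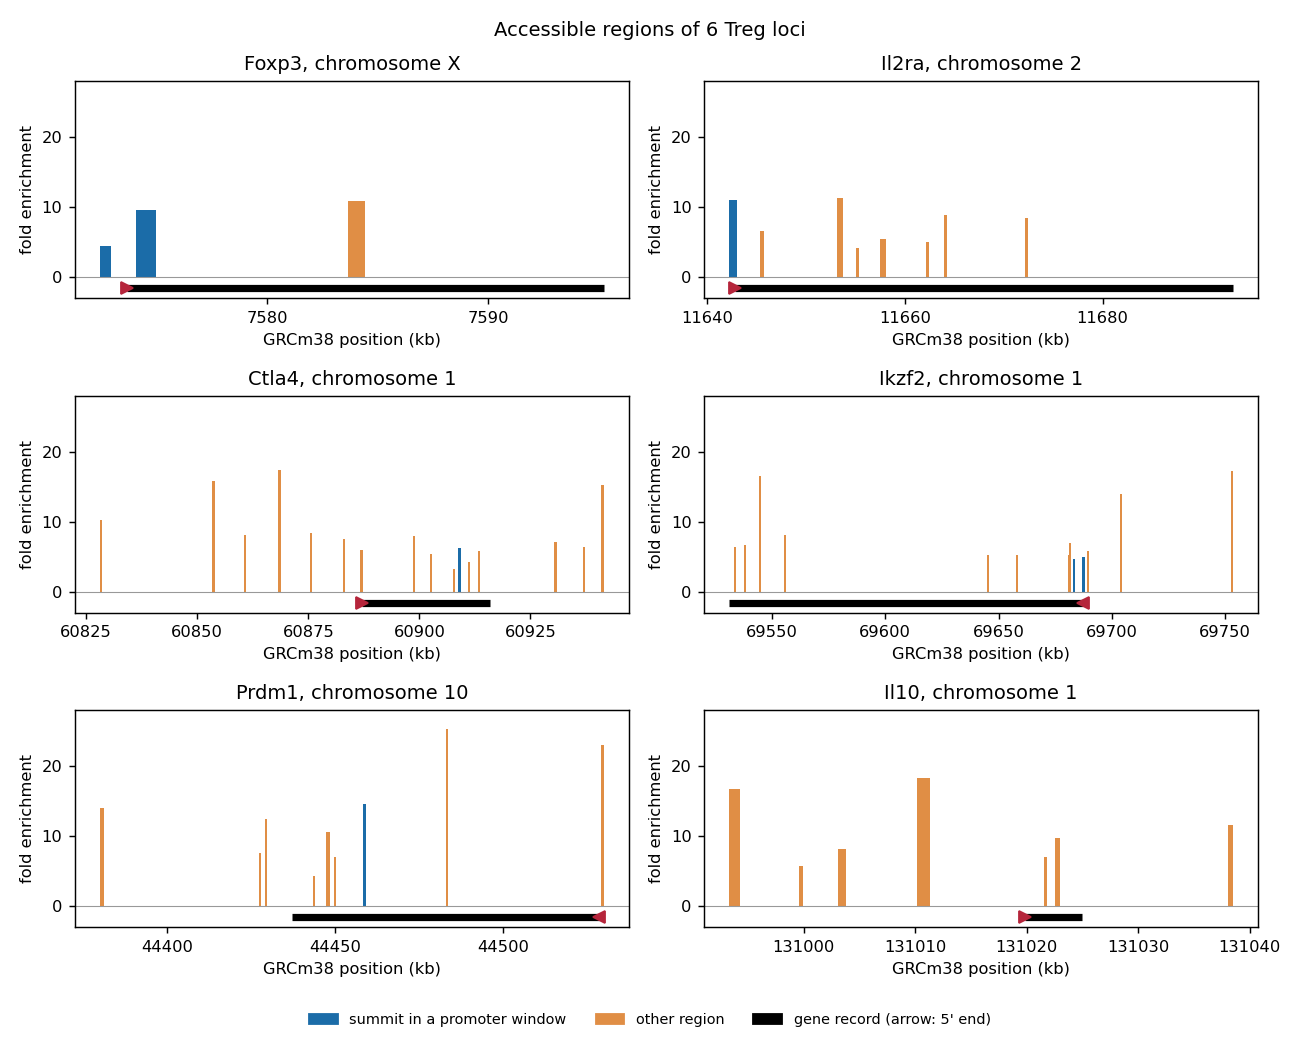
Accessible regions of the IDR-thresholded list at Foxp3, Il2ra, Ctla4, Ikzf2, Prdm1 and Il10 (horizontal axis, GRCm38 position in kb; vertical axis, fold enrichment over background), with regions whose summit lies in a promoter window in blue, other regions in orange, and the gene record as a black bar with a red arrow at its 5' end. At Prdm1 the intronic region reaches 25.3, and at Il10 no region lies in a promoter window.

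In the IDR-thresholded list the gene with most regions assigned was Akap13, a kinase anchor protein, with 31, followed by Foxp1 (29), Bach2 (28), Arid5b (23), Arhgef3 (21) and the Src family kinase Fyn (21). A further 10 genes had 19 regions each: Btg1, Cd47, Chd7, Dock10, Prkch, Prkcq, Rgs3, Runx1, Sgms1 and Trio. Chd2 and Itpr1 had 18, and Atxn7l1 and Camk2d had 17. Prkcq, which encodes the T cell receptor signalling kinase PKC theta, was the 1 gene of these 20 with no promoter region. Per 100 kb of territory none of the 20 ranked above 604 (Prkch). Of the 20 genes, 10 remained among the top 20 in the pseudoreplicated list and 7 in the upper 50% of regions by fold enrichment. The leading gene changed as well: it was Foxp1 in the pseudoreplicated list and with a limit of 50 kb, Smad7, named here after the values were seen, in the upper 50%, and Bach2 with summits counted singly.

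The 10 regions with the highest fold enrichment were of another kind. They were 247 to 498 bp wide with a single summit, and 9 of the 10 lay away from promoters. The highest were 2:69355469-69355735, in intergenic sequence −12982 bp from the start of Abcb11, at 64.1, and X:143482934-143483180, in intergenic sequence −35532 bp from that of Pak3, at 62.2. They were followed by regions nearest to Gm5426 (48.2), G6pd2 (47.4), Igf2bp3 (42.5), Rtl10 (42.5), Gm13283 (41.4), Nxph1 (38.1), Gm20594 (37.9, at its promoter) and Cdh20 (36.0). Those nearest to Gm5426, G6pd2, Nxph1 and Gm20594 aligned to the mitochondrial genome over at least 50% of their length, and that nearest to Abcb11 over 48.3%.

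Summits away from promoters were enriched for most of the motifs searched, CTCF, NF-kB, ETS, RUNX and AP-1 among them. Among 18613 such summits, the CTCF consensus CCASYAGRKGGC occurred within 50 bp of 6.44%, against 0.0806% in flanking windows 500 bp away, a log2 ratio 5.83 above that of base-shuffled versions of the motif (95% bootstrap interval over regions 5.27 to 6.55). The ETS word ACAGGAAG occurred at 10.6% (log2 ratio over shuffles 2.87, 2.71 to 3.03), the RUNX word TGTGGTTT at 4.45% (2.75, 2.55 to 2.96), the AP-1 word TGASTCA at 7.54% (2.29, 2.15 to 2.43) and the NF-kB word GGGRNTTTCC at 2.01% (3.18, 2.86 to 3.55). The composite site of BATF and IRF factors was rare, at 51 summits, and enriched (2.85, 1.94 to 3.96). Its word GAAATGASTCA contains the AP-1 word, so this enrichment was not separated from that of AP-1. The log2 ratio of summits to flanks alone was 2.60 (1.87 to 3.64) for the composite and 2.15 (2.03 to 2.30) for AP-1. The IRF word reached 2.18 (2.01 to 2.34) and the TCF/LEF word, bound by TCF1 and LEF1, 1.42 (1.19 to 1.64). Words of factors known also from other lineages were enriched as well, such as PU.1 at 4.03% (1.76, 1.57 to 1.97) and POU/OCT (1.58, 1.28 to 1.90), and MEF2 (16 matches) and C/EBP (8 matches) at few summits. The PU.1 word GAGGAAGT shares the letters AGGAAG with the ETS word ACAGGAAG, so its enrichment was not separated from that of ETS. The forkhead word, the kind of site FOXP3 can bind, was enriched weakly (0.53, 0.32 to 0.72), and the intervals of T-box (0.23, −0.13 to 0.60) and MYB (0.10, −0.08 to 0.28) included 0. Motifs of T cell factors were not tested against those of other lineages. Depleted at these summits were the NFAT word (−0.36, −0.54 to −0.19), the B cell factor EBF (−1.24, −1.97 to −0.64) and TEAD (−1.36, −1.98 to −0.85). The EBF depletion was lost in the upper 50% of regions by fold enrichment (−0.56), and the C/EBP enrichment with flanks 2000 bp away (1.60). Of 34 motifs, 24 were enriched and 3 depleted; with at least 20 matches required, a limit set after the values were seen, 21 were enriched.

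Of the 22 motifs enriched at promoter summits, 20 were also enriched at distal ones, and the difference between them was not tested. With at least 20 matches required, 18 of the 34 motifs were enriched at promoter summits. Among 10802 promoter summits, the NFY word CCAATCR occurred at 11.4% (log2 ratio over shuffles 3.74, 3.55 to 3.95), the GC-rich word of KLF and SP factors at 17.2% (0.80, 0.69 to 0.92), the ETS word CCGGAAGT at 5.87% (3.61, 3.22 to 4.08) and the CREB/ATF word TGACGTCA at 2.95% (4.46, 3.89 to 5.31). NRF1 (2.85, 1.94 to 4.09) and CTCF (2.85, 2.11 to 3.81) followed. RUNX (1.66, 1.25 to 2.10), AP-1 (1.23, 0.96 to 1.5) and NF-kB (1.53, 0.93 to 2.14) were also enriched, and TCF/LEF was not (−0.01, −0.54 to 0.42). Depleted at promoters relative to their shuffles were 4 of the 34 motifs. On the log2 ratio of summits to flanks alone, calls can differ. There TCF/LEF lay below 0 (−0.75, −1.26 to −0.32), and the interval of the E-box word CAGCTG, enriched over shuffles, included 0 (0.11, −0.04 to 0.25). For words that hold CG, such as those of ETS, CREB/ATF and NRF1, the shuffled versions kept the number of CG pairs. They did not keep the letters around those pairs. Families of factors share their words, and a match does not show which factor was bound.

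**Figure D4:**
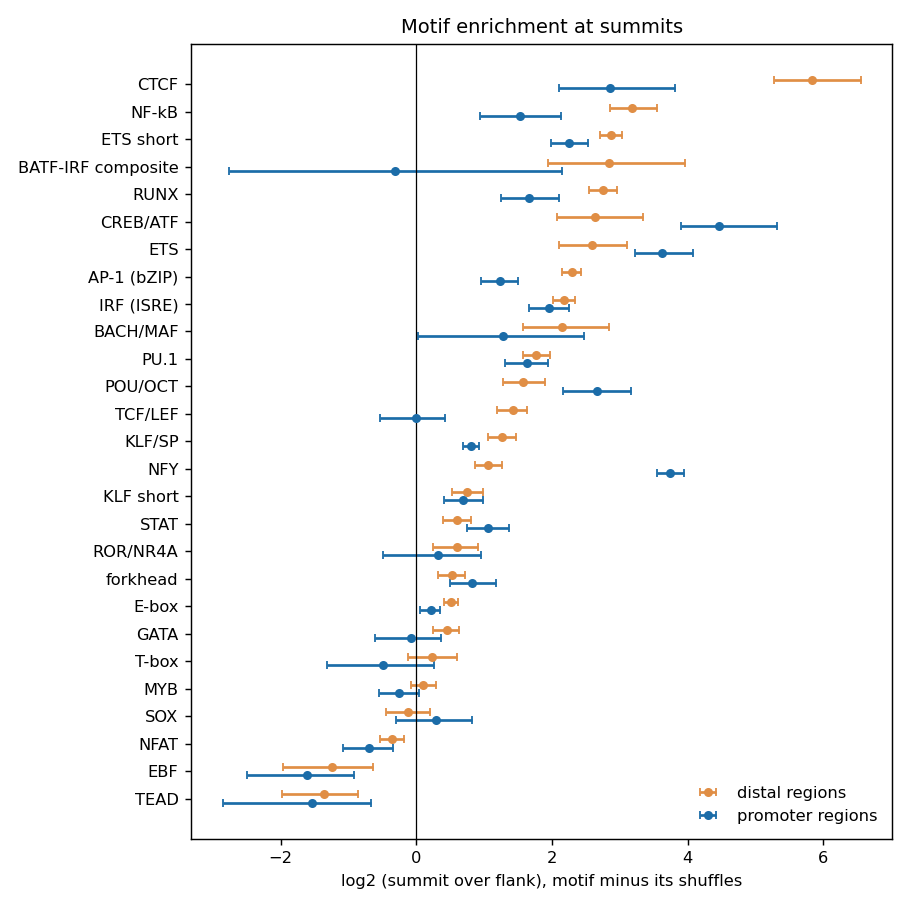
Log2 ratio of motif matches at summits over flanks, minus that of the motif's shuffled versions (horizontal axis), for motifs with at least 20 matches at distal summits, in 18613 distal (orange) and 10802 promoter regions (blue); bars are 95% bootstrap intervals over regions. CTCF is highest at distal summits (5.83) and CREB/ATF at promoters (4.46), and NFAT, EBF and TEAD lie below 0 in both.

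Over all genes, the single X chromosome of these male cells had a lower share of accessible promoters than the autosomes, and in the IDR-thresholded list those present had a slightly higher fold enrichment. Of 947 X-linked genes 35.2% had a promoter region, against 50.8% of 20692 autosomal genes, a difference of −15.6 percentage points (95% Newcombe interval −18.7 to −12.5). In the upper 3 deciles of promoter CpG content the difference was −2.23 points (−10.2 to 3.79; 81.5% of 119 genes against 83.7% of 6423), so the lower share over all genes was not separated from CpG content. The 323 promoter regions on X had a median fold enrichment of 16.4 and the 10475 on autosomes had 15.4, a difference of 0.987 (bootstrap interval 0.187 to 1.87). The difference in fold enrichment was not robust, since it was −0.0136 when each summit was counted on its own and its interval included 0 in the pseudoreplicated list (0.802, −0.141 to 1.88).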

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

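The ranked list held 142 summits on unplaced or unlocalised sequences of the mouse assembly, and 58 of them had an IDR at or below 0.05. They are part of the 87840 summits and 53708 regions given for the ranked list in the report, and enter no result on location, genes or motifs. The other 2 lists were confined to the 21 assembled chromosomes, so their count of 0 there is no reference for the 142. Of the 142 summits, 59 lay on a single unplaced sequence, 25 of them at an IDR at or below 0.05 and with a −log10 p of up to 1102. No control samples were used here, no test was run on these summits, and no biological explanation was tested.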

How the results depend on the processing

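One alternative, without regions that align to the mitochondrial genome, was chosen after seeing the data, and it changed no call. No paired analysis was possible because there was 1 group, and leaving out a replicate was not possible because the lists were taken to pool the libraries. Depth is unknown and limits every call in an unknown way. Of 753 recomputed values, 664 kept their side of the bounds or stayed within their range. Values that crossed the middle with no bound passed before or after are counted among these 664. The overlap of 50% moved nothing, since shared regions had the same start and end.

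The promoter excess (15.1-fold) was 10.8 in the pseudoreplicated list, 19.1 in the upper 50% of regions by fold enrichment, 19.96 with summits counted singly, 25.6 and 8.85 with windows of 500 and 2000 bp, and 20.3 with gene 5' ends only. For promoters, 2 lists lay above and 7 below the bounds in the upper 50% of regions (6 and 2 in the report), 1 lay below with gene 5' ends only and 6 with unmatched random lists. In the upper 50% the direction turned, with a bound passed before or after, for the Treg core (percentile 18.3), naive and resting T cell (0.015), AP-1 and BATF family (0.070) and NF-kB and NFAT lists (1.255). The effector and tissue Treg (92.9 to 2.585), effector cytokine (89.97 to 2.94), B cell (38.2 to 70.4) and erythroid lists (29.1 to 57.5) crossed the middle without passing a bound. The median promoter fold enrichments of the first 4 lists (8.61, 9.27, 11.3 and 9.56) lie below the median of all regions (13.1), which this alternative requires. For regions per locus, the lists below the bound numbered 1 in the pseudoreplicated list, 1 in the upper 50%, 4 with summits counted singly and 0 without own promoters, against 2. For the other results the cause was not tested. The X-linked excess in fold enrichment (0.987) was 0.802 in the pseudoreplicated list, 0.680 with a 500 bp window and 0.743 with gene 5' ends only, all with intervals that include 0, and −0.0136 with summits counted singly. Of the 20 genes with most regions, 10 were shared with the pseudoreplicated list, 7 with the upper 50% and 10 with a limit of 50 kb. The BATF-IRF composite at promoters turned from −0.31 to 1.72 with summits counted singly. The first value rested on 1 match at the promoter summits, and its interval was −2.76 to 2.15. With the direction kept, 18 list percentiles lost and 15 gained a call, and 20 and 10 motif ratios did. The 4 lists and the 1 motif whose direction turned, named above, are not in these counts.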

Other observations

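The test on the territory of T cell loci and the alternative without mitochondrial alignments were chosen only after the result was seen. The criteria of the other tests were written before their own values were known, most of them once the pattern they address had been noticed in the same data. The criterion against a loss of weak X-linked regions was replaced after its value had been seen.

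Single genes in the lists of other cell types had a promoter region. Among dendritic cell genes, Irf8 had 6 regions and a promoter fold enrichment of 25.6, and Tcf4 had 11.4 at its promoter. Among myeloid genes, accessible promoters included those of the transcription factors Cebpa (11.9), Cebpb (7.19, with 7 regions) and Spi1 (11.6), while Csf1r, Itgam, Lyz2, Cd14, S100a8, S100a9, Elane and Cd68 had no region assigned. Among B cell genes, Pax5 (15.4), Cr2 (17.1) and Pou2af1 (17.6) had a promoter region, and Ms4a1, Cd79a and Blnk had no region assigned. Among erythroid genes, Klf1 (15.95) and Epor (15.2) had one. Lineage factors of these lists without a promoter region included Ebf1, Spib, Batf3, Zbtb46, Gata1 and Tal1. These genes were chosen from their values, within lists fixed in advance.

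At 20477 summits away from promoters in the pseudoreplicated regions outside the IDR-thresholded list, CTCF matches lay at 7.75%, the ETS word ACAGGAAG at 7.30%, AP-1 at 6.35%, RUNX at 3.02% and NF-kB at 1.39%, and the intervals of their log2 ratios over shuffles lay above 0. The ratios of RUNX (2.03, 1.83 to 2.22) and AP-1 (1.79, 1.66 to 1.92) were lower than in the IDR-thresholded list (2.75, 2.55 to 2.96 and 2.29, 2.15 to 2.43), as was that of the ETS word (2.47, 2.32 to 2.62 against 2.87, 2.71 to 3.03). The intervals of NF-kB (2.93, 2.56 to 3.33 against 3.18, 2.86 to 3.55) and CTCF (6.15, 5.63 to 6.85 against 5.83, 5.27 to 6.55) overlapped. The interval of NFAT included 0 (−0.18 to 0.13).

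Of 10 regions with a −log10 p over 1000, up to 4549 at 12:97061375-97061857, 7 aligned to the mitochondrial genome at 90% identity or more over at least 50% of their length, against 10 of the 29405 other regions (0.0340%). This is what reads of mitochondrial DNA placed on nuclear copies of it would give. Interspersed repeats account for few of them, since 1 of the 10 had at least 50% of its bases soft-masked, and so do open promoters or CTCF sites, at 0 of the 10. The regions near Pak3 (X:143482934-143483180) and Zfp960 (17:17004586-17005526) had no alignment at 90% identity or more, and weaker ones were not counted. They stay open, as does that near Abcb11, where 48.3% of the region aligned. No biological explanation was tested, and leaving out the 17 regions that aligned left the promoter excess at 15.1-fold.

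Male cells hold a single X, yet X-linked promoter regions had a median fold enrichment of 16.4 against 15.4 on autosomes. At matched fold enrichment the −log10 p on X was 0.765 times that on autosomes (bootstrap interval 0.720 to 0.825), as a background that itself falls with copy number would give; this is a candidate explanation, since the authors' background was not measured. A loss of weak X-linked regions at the threshold was not settled: in the upper 3 CpG deciles the share of accessible promoters was 81.5% of 119 genes on X and 83.7% of 6423 on autosomes, a difference of −2.23 points (Newcombe interval −10.2 to 3.79). The criterion set in advance against this explanation, an interval that includes 0, was met. It was set aside after the value had been seen, because with 119 genes the interval also includes a loss of more than 5 points. X-linked and autosomal genes differ in function, which stays open as untested.

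Promoters of the Treg core list were accessible but low. Their median fold enrichment was 8.61 in 22 promoters, at percentile 0 of 10000 random lists of accessible promoters (median 16.4), and promoters were lower where loci were rich in regions, at 17.8 with 0 or 1 region, 15.3 with 2 to 6 and 11.8 with 7 or more. Lists matched on the number of regions of the locus had a median of 13.4 and lists matched on CpG decile 15.9. The Treg core stayed at percentile 0 of both and of lists matched on both (13.0), which argues against either as the whole cause. For CpG this holds only for content around the 5' ends of gene records, which at Ctla4 is not the promoter scored. When matched on both, the AP-1 and BATF family (11.3, percentile 1.225) and the NF-kB and NFAT list (9.56, 1.765) were also low, and the naive and resting (9.27, 5.515) and pan T cell lists (13.7, 65.1) lay within the random lists. A high local background at such loci may still contribute, since the number of regions is a stand-in for it and the background itself was not measured, and no biological explanation was tested.

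The enrichment of the ETS, RUNX and AP-1 words was not matched by their shuffled versions: the lowest ratio of motif to shuffles among them was 4.90 (4.45 to 5.40). Of the 824 summits in the IDR-thresholded list with a q-value over 0.05, 97.45% shared their region with a summit at or below 0.05. With the decile of territory length matched, the lower of the Treg core and pan T cell locus percentiles was 100. Differences between deciles of territory length thus do not account for the regions around these genes. These are the percentiles already given in the report and not a separate test.

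Both hypotheses on motifs at effector and naive loci were left undecided by their intervals. AP-1 matches lay at 15.4% of 91 distal summits of effector and tissue Treg loci and at 12% of 150 of naive and resting loci, a difference of 3.38 points (−5.22 to 13.2), with 7.54% over all distal summits. TCF/LEF matches were at 2.00% of naive and resting and 2.20% of effector and tissue Treg summits, a difference of −0.198 points (−5.82 to 3.84).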
